A study of Zea mays with 40 samples.

How the data were processed

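RNA from 3 tissues of maize plants was measured on 20 Agilent 2-colour arrays. The tissues were leaves exposed to ultraviolet-B (UV-B), shielded leaves of exposed plants, and their shielded immature ears. Each tissue had 4 RNAs at 0, 10 and 30 min. Irradiated leaf also had 2 RNAs at 60 min, each set against a 30 min RNA, so that 2 RNAs of 30 min (RNA 3 and RNA 4) were hybridised on 2 arrays and the 40 channels hold 38 RNAs. In each tissue the pairs of time points formed a loop, with 2 arrays per pair in opposite dye orientations. The arrays came from 5 slides of 4 arrays. Irradiated leaf filled slides 1 and 2, which were scanned in one session. Shielded leaf filled slide 3 and shared slide 4 with ear, which also filled slide 5, and these were scanned in another session.

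The deposited scanner files hold linear spot intensity per channel from Agilent Feature Extraction 10.5.1.1, per the file headers. The median pixel intensity of each spot and of its local background is uncorrected, per the file headers, and the processed intensity is background-subtracted and dye-normalized within the array, per the file headers. Both files deposited for an array were identical for 20 of 20 arrays, so each sample was read from the channel of its dye label. The files hold no mean pixel intensity, and median intensity was used in its place, a departure from the design fixed before the data were examined. The deposited value table holds linear intensity with 1 channel per column. Limma is named in the submitters' processing notes without settings. All 40 columns were closer to their own channel's scanner values than to the other channel's. The column medians lay between 93.1 and 93.2, except for 1 column (shielded leaf, 30 min, RNA 2) with a median of 0. Between 12.0% and 57.9% of the probes in a column stood at 0, and in 39 of 40 columns every such probe had a lower scanner signal than every other probe. The meaning of 0 is unknown, as is the normalization behind the equal medians, and zeros were treated as missing.

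Log ratios were computed with limma 3.58.1 in R 4.3.3. Background was corrected with the normexp method and an offset of 50, and each array was normalized by loess with control spots at weight 0. The 1417 control spots were then removed, leaving 42034 probes, and spots marked as outliers by the scanner software were set to missing (0.272% of values, in 1438 probes). A probe was kept for a tissue when it was well above background in a share of at least 3 in 4 of the channels of some time point. Irradiated leaf had only 2 channels at 60 min, and there both were required. Probe A_92_P009368, for example, entered irradiated leaf through these 2 channels alone. The filter kept 36990 probes for irradiated leaf, 33207 for shielded leaf and 37790 for ear. The 60 min tests covered 36796 probes.

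All 20 arrays entered 1 linear model (lmFit and eBayes), with a coefficient per tissue and time and a dye effect per probe, so that the tissues shared 1 estimate of the spread. It had 12 residual and 3.60 prior degrees of freedom, and a prior SD of 0.122. The changes against 0 min and between later times, the moderated F test over the times of a tissue, and the differences of the changes between tissues were tested with limma and adjusted by Benjamini-Hochberg at 0.05. For 60 against 0 min, no array held both times, and the change was the sum of the 30 to 60 min and 0 to 30 min changes. Tissues at 0 min were compared with limma's separate-channel analysis (Aquantile, then lmscFit with a within-spot correlation of 0.744), because no array held 2 tissues. Levels of single probes are normalized log2 intensity from that analysis, and their means are over RNAs. The separate-channel analysis takes no missing values, so spots marked by the scanner software stayed in it. Every p-value in the text, unless named otherwise, is from these limma fits.

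On simulated data with 200 changed probes, the 30 against 0 min test in irradiated leaf recovered 83.6% of 1.5-fold and 94.0% of 2-fold changes, and 4.66% of its calls were false. Shielded leaf gave 83.6%, 94.0% and 7.04%, and ear gave 79.1%, 98.5% and 5.64%. For 60 against 0 min these were 46.3%, 77.6% and 7.45%. For ear against shielded leaf at 0 min they were 32.8%, 100% and 6.63%. The simulated time changes had noise drawn independently for each probe and array, with the same spread in all tissues and times. The simulation of 0 min gave every probe the same noise. Correlated probes and arrays of unequal spread were not simulated, so these rates need not hold for the real arrays.

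Median signal per channel was 63 to 147 in irradiated leaf, 58.5 to 89 in shielded leaf and 117 to 222 in ear. Median signal over background was 2.17 to 5.03, 1.91 to 3.97 and 3.71 to 7.99. The share of probes well above background was 70.7% to 91.4%, 68.9% to 84.9% and 84.2% to 93.1%. The number of arrays limits the precision.

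The files pair probes with 39174 transcript identifiers, of which 2505 have more than 1 probe, and 27161 probes carry an assembled-transcript (TC) number. These do not pair with gene names. Only 2 identifiers, on 4 probes, matched the gene table supplied, so the 31 gene lists and the cell type lists fixed before the data were examined had 0 measured members and were not analysed here. The rule for named genes (the largest changes among probes past the threshold with the same sign on every direct array) was therefore applied to probe IDs. It was limited to the 2 with the largest rise and the 2 with the largest fall in irradiated leaf at 30 against 0 min. Probes whose identifier is itself a gene name (MuDR, cohesin, shugoshin and ameiotic1) were chosen after the identifiers were seen, as were 2 groups of probes that stood at least 8-fold apart between ear and shielded leaf at 0 min.

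Alternatives fixed before the data were examined were Agilent's processed intensity, no background subtraction, median centring, the deposited value table, a separate-channel fit, no filter and a strict filter on dim probes, no dye effect, each tissue alone and the data without the 60 min arrays. Slide as a block, each slide alone, a replicate block, array quality weights, a trended robust prior, a 1.5-fold minimum and each array left out in turn were fixed then too. Keeping the spots marked by the scanner software, and slide as a term for ear against shielded leaf at 0 min, were added after seeing the data. Other splits of the samples into groups of the same sizes were tested for each count of probes between groups of 4 RNAs.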

Results

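The series measured how the maize transcriptome changes within 1 h of UV-B exposure of the top leaves, in the exposed leaves and in shielded parts of exposed plants. There were 4 RNAs each at 0, 10 and 30 min for irradiated leaf, shielded leaf and shielded ear, and 2 RNAs at 60 min for irradiated leaf. Ear channels were brighter than shielded leaf channels by median signal (117 to 222 against 58.5 to 89) and overlapped with those of irradiated leaf (63 to 147). The median signal of ear stood 3.71 to 7.99 times above background, against 2.17 to 5.03 in irradiated leaf and 1.91 to 3.97 in shielded leaf. Changes below are log2 values with their standard error, higher or lower at the later time.

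Before exposure, ear and shielded leaf differed in most of the probes measured in both. Of 32600 probes, 10192 were higher in ear and 11809 higher in leaf. At least 8-fold differences were found for 1143 probes higher in ear and 1272 higher in leaf. Irradiated leaf at 0 min and shielded leaf at 0 min differed in 4062 of 32890 probes, of which 2077 were higher in irradiated leaf and 499 differed at least 2-fold. The 2 leaf positions shared no slide and no scan session, so leaf position and batch cannot be told apart. Shielded leaf shared its session with ear, but its 0 min RNAs were on slide 3 and those of ear on slides 4 and 5. No slide thus held both tissues at 0 min.

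Irradiated leaves changed within 10 min. Against 0 min, 1029 probes were higher and 680 lower, with a median change of 1.40-fold among them, and 123 rose and 100 fell at least 2-fold. On both arrays that set these times against each other, 1674 of the 1709 moved the same way, but the calls rest in part on these arrays. Probe A_92_P024104 rose by 3.99 ± 0.33 (n = 4 RNAs per time, limma adjusted p = 1.27e-05), from a mean level of 10.9 ± 0.70 to 14.7 ± 0.33 (SD). Probe A_92_P025151 fell by 1.96 ± 0.23 (limma adjusted p = 0.000141), and A_92_P020528 fell by 2.02 ± 0.38 (limma adjusted p = 0.00565). Probe A_92_P030211 stood at 1.65 ± 0.52 (limma adjusted p = 0.0882). The count was 541 with irradiated leaf fitted alone and 695 without one 0 against 10 min array (10 min RNA 1 and 0 min RNA 4), rose to 2695 without one 10 against 30 min array (10 min RNA 3 and 30 min RNA 2), and median centring gave 485 higher and 129 lower. A_92_P020528 lost its call with irradiated leaf alone, where its change was the same, and without either 0 against 10 min array, where it was -1.68 and -1.98.

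At 30 min fewer probes passed the test in irradiated leaf than at 10 min, except under median centring (934 against 614). Of 625 probes, 373 were higher and 252 lower, with a median change of 1.45-fold. As many were called in 4 of 34 splits of the RNAs, the real one included (highest other 814), so chance cannot be excluded for this count. The probes called at both times were 271 higher and 197 lower and none in opposite directions, but both changes share the 0 min RNAs. A_92_P024104 stood 2.28 ± 0.33 higher (limma adjusted p = 0.00257) and A_92_P030211 2.20 ± 0.52 higher (limma adjusted p = 0.0435). The level of A_92_P030211 was 10.2 ± 2.08 (SD) over the 30 min RNAs, against 8.26 ± 0.19 at 0 min. Its 30 min RNAs thus varied about as much as it rose, while the standard error rests on a spread shared by all tissues and times. A_92_P025151 fell by 2.10 ± 0.23 (limma adjusted p = 0.000458) and A_92_P020528 fell by 2.07 ± 0.38 (limma adjusted p = 0.0109). Each of the 4 had the same sign on both direct arrays, as the rule that chose them required. Between 10 and 30 min, 4 probes rose and 28 fell, and chance cannot be excluded (as many in 6 of 34 splits, highest other 425). That count of 32 ranged from 1, without the 10 against 30 min array of 30 min RNA 1 and 10 min RNA 4, to 133, without that of 10 min RNA 3 and 30 min RNA 2, and under median centring 17 rose and 6 fell. Under median centring 872 probes were higher and 62 lower at 30 against 0 min. With irradiated leaf fitted alone the count was 78, with no call for A_92_P024104, A_92_P030211 or A_92_P020528, whose changes were the same. Without the 0 against 30 min array of 30 min RNA 3 the count was 105, and A_92_P030211 (1.75) and A_92_P020528 (-1.64) lost their calls. A_92_P030211 was also lost without any of 3 other irradiated leaf arrays, with Agilent's processed signals, the deposited value table, no dye effect, slide as a block or array quality weights, with changes of 1.72 to 2.60 in these settings, and A_92_P020528 within slide 1 (-1.73).

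**Figure D1:**
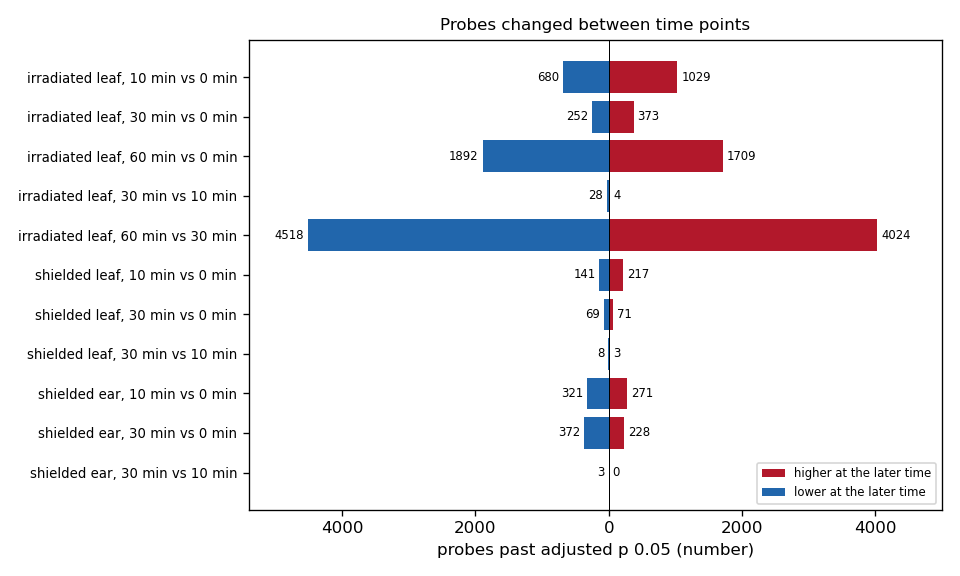
Number of probes past an adjusted p of 0.05 in each comparison of time points, higher at the later time to the right and lower to the left, from limma with loess normalization. The 60 against 30 min comparison in irradiated leaf has the longest bars, 4024 higher and 4518 lower, and rests on 2 arrays.

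At 60 min many probes of irradiated leaf stood apart from 30 min. Between 30 and 60 min 4024 probes rose and 4518 fell, by a median of 1.34-fold, and 229 and 319 of them changed at least 2-fold. Against 0 min, 1709 probes were higher and 1892 lower at 60 min. Of the 1029 probes higher at 10 min, 187 were higher and 78 lower at 60 min, with a median of 0.04, and 447 fell and 115 rose between 30 and 60 min. Of the 680 probes lower at 10 min, 196 were lower and 35 higher at 60 min, with a median of -0.28, and 169 rose and 89 fell between 30 and 60 min. These changes share RNAs, which alone correlates them. Across probes the 60 min change correlated with the 10 min change at r = 0.197 (0.188 for simulated unchanged groups), with a covariance of 0.0133 (0.00269 simulated), and with the 30 min change at 0.231 (0.407 simulated), with a covariance of 0.0126 (0.00583 simulated). The changes from 0 to 30 and from 30 to 60 min correlated at -0.296 (-0.411 simulated), with a covariance of -0.0164 (-0.00590 simulated). A_92_P020528, lower at 10 and 30 min, rose by 3.68 ± 0.46 between 30 and 60 min (limma adjusted p = 7.2e-05, 2 of 2 arrays), and A_92_P030211 fell by 2.36 ± 0.63 (limma adjusted p = 0.0137). At 60 min A_92_P024104 was 3.32 ± 0.52 above 0 min (limma adjusted p = 0.00111) and A_92_P025151 stood at -1.90 ± 0.36 against 0 min (limma adjusted p = 0.00377). Only 2 RNAs and 2 arrays stand behind 60 min. The count for 60 against 30 min was 16330 under median centring (6325 higher), 2118 within slide 2 and 2954 without the array of 60 min RNA 1. For 60 against 0 min it was 306 under median centring (103 higher and 203 lower) and 1341 without that array.

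Probes named in the files for the Mutator transposon MuDR and for meiosis genes were few. All 4 MuDR probes rose between 30 and 60 min in irradiated leaf, MUDR-TIRA by 0.33 ± 0.08, MUDRA-21 by 0.39 ± 0.11, MUDRA by 0.36 ± 0.09 and MUDRB by 0.37 ± 0.10 (limma adjusted p = 0.0054, 0.017, 0.00776 and 0.0163, each on 2 of 2 arrays). Under median centring their changes were 0.01, 0.00, 0.06 and -0.15, none past the test, while all 4 passed with Agilent's processed signals and with the deposited value table. Their calls were also lost within slide 2, where the changes were the same, and without the array of 60 min RNA 1, where they were 0.20, 0.39, 0.15 and 0.20. The calls of MUDRA-21, MUDRA and MUDRB were lost with irradiated leaf alone or no dye effect, which left the changes the same. Against 0 min at 60 min, MUDRA passed at 0.44 ± 0.11 (limma adjusted p = 0.0214) but not under median centring (0.30), without that array (0.23), or with irradiated leaf alone or no dye effect (0.44). No MuDR probe passed in any comparison of 0, 10 and 30 min in the 3 tissues. Of 13 probes for subunits of cohesin, the complex that holds sister chromatids together, 2 passed between 30 and 60 min. A single ZmRAD21 probe of 7 rose by 0.29 ± 0.09 (limma adjusted p = 0.0336, 1 of 2 arrays), and the other 6 changed by -0.02 to 0.10 (limma adjusted p = 0.288 to 0.95). One ZmSMC1 probe fell by 0.37 ± 0.08 (limma adjusted p = 0.00392, 2 of 2 arrays), and the other stood at 0.07 ± 0.39 (limma adjusted p = 0.926). Both calls were lost within slide 2, with irradiated leaf alone, with no dye effect and without the array of 60 min RNA 1 (0.13 and -0.20, the changes being the same in the other settings). The ZmRAD21 probe was also lost with 6 further settings, median centring among them (0.25 to 0.60), and the ZmSMC1 probe with the separate-channel fit (-0.43). The same ZmSMC1 probe passed at 60 against 0 min with -0.45 ± 0.10 (limma adjusted p = 0.0125). That call was lost with irradiated leaf alone, no dye effect, Agilent's processed signals, median centring, the separate-channel fit and without the array of 60 min RNA 1. The change was -0.28 without that array and -0.69 to -0.44 in the others. The shugoshin probe and the ameiotic1 probes (3 tested in ear, 2 in irradiated leaf, 1 in shielded leaf) passed in no comparison of times in which they were tested.

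Shielded leaves of the exposed plants changed too. At 10 min 217 probes were higher and 141 lower, with a median change of 1.54-fold, and at 30 min 71 were higher and 69 lower. A_92_P024104 rose by 4.30 ± 0.33 at 10 min (limma adjusted p = 5.92e-06) and stood 2.24 ± 0.33 higher at 30 min (limma adjusted p = 0.0041). A_92_P025151 fell by 1.87 ± 0.23 and 1.82 ± 0.23 (limma adjusted p = 0.000289 and 0.00145). A_92_P020528 stood at -1.56 ± 0.38 and -1.51 ± 0.38 without passing (limma adjusted p = 0.0652 and 0.143). Between 10 and 30 min, 3 probes rose and 8 fell, a count of 11 that was 0 under median centring, with shielded leaf alone, without the array of 30 min RNA 3 and 0 min RNA 2 and without that of 10 min RNA 1 and 0 min RNA 4. It was at most 5 with any 1 of the 6 arrays left out, and 795 with array quality weights. The 10 min count was 118 under median centring (98 higher and 20 lower), 2898 with array quality weights and 110 without one 0 against 10 min array (10 min RNA 1 and 0 min RNA 4). The 30 min count was 28 under median centring, 773 with array quality weights and 24 without the 0 against 30 min array of 30 min RNA 3. Both counts were higher within slide 3, with Agilent's processed signals, with no background subtraction and from the deposited value table. With each tissue fitted alone the 10 min count rose, and it was then about as large as that of irradiated leaf.

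Most probes that changed in shielded leaf changed in the same direction in irradiated leaf. At 10 min 156 probes were higher in both (6.62 for independent lists) and 109 lower in both (2.91). At 30 min 49 were higher in both (0.779) and 53 lower in both (0.529), and none was called in opposite directions at either time. Across all 32890 probes the changes correlated with r = 0.658 at 10 min and 0.502 at 30 min. Probes are not independent replicates. The test of the difference between the leaf positions called 0 probes in limma at both times, with 1876 probes at an unadjusted p under 0.05 at 10 min and 1526 at 30 min. Without any difference, a share of about 0.05 of the 32890 probes is expected there, which is near both numbers. Neither number shows that the changes were the same. The separate-channel fit called 50 and 0, array quality weights gave 117 at 10 min, and leaving out one 10 against 30 min array of irradiated leaf (10 min RNA 3) gave 23.

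**Figure D2:**
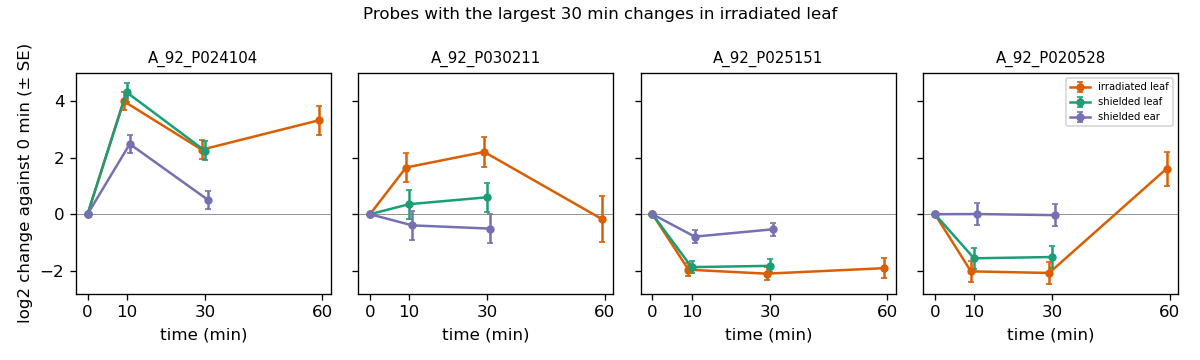
Log2 change against 0 min, with its standard error, of the 2 probes that rose most and the 2 that fell most in irradiated leaf at 30 min, over time in minutes, for irradiated leaf, shielded leaf and shielded ear. A_92_P024104 rose by 3.99 in irradiated leaf, 4.30 in shielded leaf and 2.48 in ear at 10 min, and A_92_P025151 fell in both leaf positions.

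Ears, which were shielded, changed too. At 10 min 271 probes were higher and 321 lower, and at 30 min 228 were higher and 372 lower, 97 of the latter at least 2-fold. Of these, 88 were higher and 190 lower at both times, but both changes share the 0 min RNAs. For the 30 min count chance cannot be excluded, since as many probes were called in 2 of 34 splits of the RNAs, the real one included (highest other 712). A_92_P024104 rose in ear at 10 min by 2.48 ± 0.33 (limma adjusted p = 0.000914) and stood at 0.50 ± 0.33 at 30 min (limma adjusted p = 0.659). Between 10 and 30 min 3 probes fell, a count that ranged from 1, without the 0 against 30 min array of ear 30 min RNA 3 or either 0 against 10 min array, to 72, without the 10 against 30 min array of ear 30 min RNA 1. The 10 min count was 58 and the 30 min count 7 with ear fitted alone, and under median centring they were 159 (89 higher and 70 lower) and 147 (37 higher and 110 lower). Without the 0 against 30 min array of ear 0 min RNA 1, the 30 min count was 36.

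The difference between ear and leaf changes was tested itself, and its counts varied with the arrays left out. Against irradiated leaf, 236 probes moved higher and 477 lower in ear at 10 min, and 165 and 315 at 30 min. Against shielded leaf, 66 moved higher and 95 lower at 10 min, and 40 and 62 at 30 min. Other splits reached both counts against irradiated leaf and the 30 min count against shielded leaf, so chance cannot be excluded for these. The 30 min change of A_92_P025151 was 1.57 ± 0.32 higher in ear than in irradiated leaf (limma adjusted p = 0.0258). Against shielded leaf it did not pass (1.29 ± 0.32, limma adjusted p = 0.0936). This probe was chosen for its fall in irradiated leaf at 30 min, which enters the first of these differences. Across probes, ear and shielded leaf changes correlated with r = 0.191 at 10 min and -0.088 at 30 min, and ear and irradiated leaf changes with 0.148 and 0.001. At 10 min 61 probes were still higher in both ear and irradiated leaf (7.11 for independent lists), 24 lower in both (5.66) and 15 opposite. At 30 min 3 were higher in both (2.13), 10 lower in both (2.41) and 10 opposite. For ear and shielded leaf at 10 min, 37 were higher in both (1.44), 7 lower in both (1.11) and 3 opposite. At 30 min 1 was higher in both ear and shielded leaf (0.402), 7 were lower in both (0.654) and 1 was opposite. Under median centring the counts against irradiated leaf were 109 at 10 min and 342 at 30 min (24 higher and 318 lower), and those against shielded leaf were 14 (8 higher and 6 lower) and 3 (0 higher and 3 lower). With 1 array left out at a time, the counts against shielded leaf ranged from 30 to 236 at 10 min and from 4 to 213 at 30 min. Both lowest counts came without a shielded leaf array, of 10 min RNA 1 and 0 min RNA 4 for 10 min and of 30 min RNA 3 and 0 min RNA 2 for 30 min. Both highest came without the 0 against 30 min array of ear 30 min RNA 3. Against irradiated leaf they ranged from 240, without the irradiated leaf array of 10 min RNA 1 and 0 min RNA 4, to 1430, without that of 10 min RNA 3 and 30 min RNA 2, at 10 min. At 30 min they ranged from 61, without the 0 against 30 min array of ear 0 min RNA 1, to 866, without the irradiated leaf array of 30 min RNA 1 and 10 min RNA 4.

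Within each tissue the 10 and 30 min changes share the 0 min RNAs, which alone correlates them. The correlation across probes was 0.802 in irradiated leaf, 0.664 in shielded leaf and 0.786 in ear, against 0.504, 0.502 and 0.50 for simulated unchanged groups with the same 0 min arrays. The covariance was 0.0293, 0.0141 and 0.0221, against 0.00592, 0.00633 and 0.00576 in the simulation. From arrays without a shared RNA, the correlation was 0.365, 0.459 and 0.331. Taking all times of a tissue together, limma's moderated F test called 7123 probes in irradiated leaf, 335 in shielded leaf and 691 in ear, and 1272 in irradiated leaf without the 60 min arrays. These counts were 10906, 106 and 182 under median centring, and 2585, 378 and 9 with each tissue fitted alone. They dropped to 3498 in irradiated leaf without the array of 60 min RNA 1 and to 246 in ear without the 0 against 30 min array of ear 0 min RNA 1. In shielded leaf the count was 111 without the array of 10 min RNA 1 and 0 min RNA 4, 167 without the other 0 against 10 min array and 181 without the 0 against 30 min array of 30 min RNA 3.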

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

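The test of ear changes against noise was chosen after the result was seen, and the other tests of this part were set before.

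The difference between ear and leaf changes was tested. At 10 min 161 probes differed between ear and shielded leaf, and no other split called as many (1 of 32 splits, the real one included and the lowest possible, highest other split 113). At 30 min there were 102, and chance cannot be excluded (as many in 3 of 32, highest other 210). Between ear and irradiated leaf 713 probes differed at 10 min (as many in 2 of 32, highest other 862) and 480 at 30 min (as many in 3 of 32, highest other 889), and chance cannot be excluded for either. With 1 array left out, the counts against shielded leaf fell to 30 at 10 min (without shielded leaf 10 min RNA 1 and 0 min RNA 4) and 4 at 30 min (without shielded leaf 30 min RNA 3 and 0 min RNA 2). Those against irradiated leaf fell to 240 (without irradiated leaf 10 min RNA 1 and 0 min RNA 4) and 61 (without ear 0 min RNA 1 and 30 min RNA 4). A_92_P025151 was among the 480, its 30 min change 1.57 higher in ear than in irradiated leaf (limma adjusted p = 0.0258). It was chosen for its fall in irradiated leaf at 30 min, which enters that difference, and against shielded leaf it did not pass (1.29, limma adjusted p = 0.0936).

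Ear changes that are unlike leaf changes could be noise, which correlates with nothing, but the 10 and 30 min changes of ear from arrays without a shared RNA correlated across probes with r = 0.331. They could also be unlike because few probes are measured well in both tissues, but among the 5318 probes that were brightest in both, ear and shielded leaf changes at 30 min correlated with r = -0.084. The first test argues against noise as the whole of the ear changes. Only 54.8% of probes had the same sign at both times, so noise stays open for many single probes. The second test argues against its explanation at 30 min, the only time it covered. Tissue, which the design names, stays open as an untested biological explanation. So does the batch, since ear shared only slide 4 with shielded leaf and none with irradiated leaf.

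Single RNAs stood apart in 5 of 108 groups of 4 values, which were levels of single probes, signal over background or the share of probes well above background. Chance gives about 1 in 20, so this number can be expected by chance. The statistic is the gap to the nearest other RNA divided by the range. A_92_P025151 in ear at 0 min was 10.3 in RNA 3 and 9.40 to 9.49 in the others (0.907). A_92_P020528 in ear at 10 min was 6.44 in RNA 1 and 6.32 in the others (0.943). MUDR-TIRA (A_92_P012404) in ear at 10 min was 7.29 in RNA 1 and 7.56 to 7.61 in the others (0.837). A_92_P025151 in irradiated leaf at 0 min was 9.84 in RNA 1 and 9.17 to 9.21 in the others (0.936). MUDRA (A_92_P031891) in shielded leaf at 30 min was 7.09 in RNA 4 and 7.71 to 7.76 in the others (0.927).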

How the results depend on the processing

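Counts are of probes past the threshold. Keeping the scanner-marked spots, and slide as a term for ear against shielded leaf at 0 min, were the only settings chosen after seeing the data. Counts of probes stayed within 1.5 times of the reported count in 184 of 327 cases with another setting and in 119 of 192 with an array left out. Correlations moved by less than their leave-one-out spread in 79 of 90 cases with another setting. Calls of named probes held in 265 of 310 cases with another setting and 134 of 150 with an array left out, were lost in 44 and 16, and turned in 1. That was MUDRB, A_92_P034510, between 30 and 60 min, at -0.15 under median centring. Ear against shielded leaf at 0 min (22001 probes) and irradiated against shielded leaf at 0 min (4062) stayed within 1.5 times with quantile normalization and with no filter on dim probes. The same held with each array that carried a 0 min RNA of the compared tissues left out and, for ear, with slide as a term. The cause of moved counts was not tested. Each tissue alone, each slide alone and left-out arrays hold fewer arrays, the 1.5-fold minimum removes small changes, and the filters change the number of probes tested. Fewer arrays do not account for every move. At 10 against 0 min the shielded leaf count rose with the tissue alone and within slide 3, while those of irradiated leaf and ear fell with the tissue alone. Array quality weights, higher for less spread, were 1.02 to 8.71 in shielded leaf, 0.476 to 1.85 in irradiated leaf and 0.561 to 0.995 in ear, whereas the model shared 1 spread. The 31 gene lists had no measured member, so their tests and alternatives (camera with an estimated correlation, fry, the mean of a gene's probes) were not run. Differences between tissues with each tissue or slide alone, and 60 min comparisons without the 60 min arrays, have no value. Signal over background, lowest in shielded leaf at 1.91 to 3.97, limits what dim probes can show.

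With Agilent's processed signals, irradiated leaf had 1094 at 10 against 0 min, 291 at 30 against 0 min, 2157 at 60 against 0 min and 13 at 30 against 10 min. Shielded leaf had 595 at 10 against 0 min, 298 at 30 against 0 min and 26 (14 higher, 12 lower) at 30 against 10 min. Ear had 98 at 10 against 0 min, 87 (23 higher, 64 lower) at 30 against 0 min and 1 (1 higher, 0 lower) at 30 against 10 min. The F test called 555 in shielded leaf and 112 in ear. The difference of changes gave 69 at 10 min and 59 at 30 min for ear against shielded leaf, and 135 (61 higher, 74 lower) at 10 min and 42 (20 higher, 22 lower) at 30 min for ear against irradiated leaf. R across probes was 0.479 at 10 min for irradiated leaf and shielded leaf, and 0.117 at 10 min for shielded leaf and ear.

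With no background subtraction, shielded leaf had 581 at 10 against 0 min, 316 at 30 against 0 min and 45 at 30 against 10 min. Ear had 0 at 30 against 10 min. 560 probes in shielded leaf passed the F test. Tests of differences gave 2 (2 higher, 0 lower) at 10 min for irradiated leaf against shielded leaf, and 254 at 10 min and 216 at 30 min for ear against shielded leaf.

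With median centring, irradiated leaf had 614 (485 higher, 129 lower) at 10 against 0 min, 934 (872 higher, 62 lower) at 30 against 0 min, 306 (103 higher, 203 lower) at 60 against 0 min, 23 (17 higher, 6 lower) at 30 against 10 min and 16330 at 60 against 30 min. Shielded leaf had 118 (98 higher, 20 lower) at 10 against 0 min, 28 at 30 against 0 min and 0 at 30 against 10 min. Ear had 159 (89 higher, 70 lower) at 10 against 0 min and 147 (37 higher, 110 lower) at 30 against 0 min. By the F test, 10906 in irradiated leaf, 106 in shielded leaf and 182 in ear passed. The difference of changes gave 14 (8 higher, 6 lower) at 10 min and 3 (0 higher, 3 lower) at 30 min for ear against shielded leaf, and 109 at 10 min and 342 (24 higher, 318 lower) at 30 min for ear against irradiated leaf. R across probes was 0.649 at 30 min for irradiated leaf and shielded leaf, 0.278 at 10 min for shielded leaf and ear, and 0.235 at 10 min and -0.122 at 30 min for irradiated leaf and ear.

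From the deposited value table, irradiated leaf had 10 at 30 against 10 min. Shielded leaf had 735 at 10 against 0 min, 423 at 30 against 0 min and 91 (49 higher, 42 lower) at 30 against 10 min. Ear had 183 at 10 against 0 min and 119 at 30 against 0 min. The F test called 772 in shielded leaf and 176 in ear. Tests of differences gave 2 (2 higher, 0 lower) at 10 min and 6 at 30 min for irradiated leaf against shielded leaf, 165 at 30 min for ear against shielded leaf, and 286 at 10 min and 146 at 30 min for ear against irradiated leaf.

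In the separate-channel fit, irradiated leaf had 1310 at 30 against 0 min and 182 (66 higher, 116 lower) at 30 against 10 min. Shielded leaf had 290 at 30 against 0 min and 140 (67 higher, 73 lower) at 30 against 10 min. Ear had 1269 at 10 against 0 min, 1208 at 30 against 0 min and 116 (18 higher, 98 lower) at 30 against 10 min. 582 probes in shielded leaf and 1488 in ear passed the F test. The difference of changes gave 50 (46 higher, 4 lower) at 10 min for irradiated leaf against shielded leaf, 487 at 10 min and 589 (167 higher, 422 lower) at 30 min for ear against shielded leaf, and 1385 at 10 min and 1270 at 30 min for ear against irradiated leaf.

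With no filter on dim probes, shielded leaf had 5 at 30 against 10 min. With the strict filter on dim probes, irradiated leaf had 58 at 30 against 10 min. Shielded leaf had 34 at 30 against 10 min. With no dye effect, irradiated leaf had 835 at 10 against 0 min, 219 at 30 against 0 min, 1496 at 60 against 0 min, 17 at 30 against 10 min and 4723 at 60 against 30 min. Shielded leaf had 207 at 10 against 0 min, 60 at 30 against 0 min and 7 at 30 against 10 min. Ear had 326 at 10 against 0 min and 278 at 30 against 0 min. By the F test, 3628 in irradiated leaf, 188 in shielded leaf and 325 in ear passed. Tests of differences gave 59 at 10 min and 22 at 30 min for ear against shielded leaf, and 273 at 10 min and 134 at 30 min for ear against irradiated leaf. With each tissue alone, irradiated leaf had 541 at 10 against 0 min, 78 at 30 against 0 min, 1193 at 60 against 0 min, 4 at 30 against 10 min and 5069 at 60 against 30 min. Shielded leaf had 556 at 10 against 0 min and 0 at 30 against 10 min. Ear had 58 at 10 against 0 min, 7 at 30 against 0 min and 0 at 30 against 10 min. The F test called 2585 in irradiated leaf and 9 in ear. Without the 60 min arrays, irradiated leaf had 56 at 30 against 10 min. Shielded leaf had 31 at 30 against 10 min. Ear had 21 at 30 against 10 min. 1272 probes in irradiated leaf passed the F test. With slide as a block, shielded leaf had 26 at 30 against 10 min. Ear had 5 at 30 against 10 min. The difference of changes gave 1 at 10 min for irradiated leaf against shielded leaf. With array quality weights, irradiated leaf had 371 at 30 against 0 min and 1818 at 60 against 0 min. Shielded leaf had 2898 at 10 against 0 min, 773 at 30 against 0 min and 795 at 30 against 10 min. Ear had 313 at 30 against 0 min. By the F test, 2781 in shielded leaf passed. Tests of differences gave 117 at 10 min for irradiated leaf against shielded leaf, 663 at 10 min and 347 at 30 min for ear against shielded leaf, and 233 at 30 min for ear against irradiated leaf. With the trended and robust empirical Bayes prior, irradiated leaf had 58 at 30 against 10 min. Shielded leaf had 30 at 30 against 10 min. Ear had 12 at 30 against 10 min. Requiring at least 1.5-fold, irradiated leaf had 637 at 10 against 0 min, 274 at 30 against 0 min, 1499 at 60 against 0 min and 2100 at 60 against 30 min. Shielded leaf had 197 at 10 against 0 min and 86 at 30 against 0 min. Ear had 265 at 10 against 0 min and 275 at 30 against 0 min. The difference of changes gave 315 at 30 min for ear against irradiated leaf. With the spots marked by the scanner software kept, shielded leaf had 4 at 30 against 10 min. Over only probes called in either tissue, r across probes was 0.828 at 10 min and 0.825 at 30 min for irradiated leaf and shielded leaf, 0.372 at 10 min for shielded leaf and ear, and 0.304 at 10 min and 0.092 at 30 min for irradiated leaf and ear.

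Within slide 1, irradiated leaf had 1275 at 30 against 0 min and 363 at 30 against 10 min. Within slide 2, irradiated leaf had 0 at 30 against 10 min and 2118 at 60 against 30 min. Within slide 3, shielded leaf had 925 at 10 against 0 min, 484 at 30 against 0 min and 94 at 30 against 10 min. Within slide 4, shielded leaf had 0 at 30 against 10 min. Ear had 219 at 30 against 0 min. Within slide 5, ear had 321 at 10 against 0 min, 4 at 30 against 0 min and 5 at 30 against 10 min.

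The RNA numbers were not shown to pair the samples. Correlations of the deviations of same-numbered RNAs lay between -0.161 and 0.050 for irradiated and shielded leaf, -0.175 and 0.093 for ear and irradiated leaf, and -0.099 and 0.048 for ear and shielded leaf, none above 0.1 in 6 pairs each. Their medians of -0.017, -0.099 and -0.029 stood above the -0.113, -0.150 and -0.085 of all other array pairs. Those pairs differed in times or dye orientation, and some of them held the same RNA numbers. With the replicate block, which spans 2 columns that also hold the dye effect, the 30 against 10 min counts were 58 in irradiated leaf, 41 in shielded leaf and 38 in ear, and no other count moved by over 1.5 times.

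With each array left out in turn (a time left with 1 RNA is assumed to vary like the others), irradiated leaf had 695 to 2695 at 10 against 0 min, 105 to 976 at 30 against 0 min, 1 to 133 at 30 against 10 min, 1341 to 3636 at 60 against 0 min and 2954 to 9113 at 60 against 30 min. Shielded leaf had 110 to 310 at 10 against 0 min, 24 to 107 at 30 against 0 min and 0 to 5 at 30 against 10 min. Ear had 360 to 796 at 10 against 0 min, 36 to 703 at 30 against 0 min and 1 to 72 at 30 against 10 min. The F test called 3498 to 8118 in irradiated leaf, 246 to 914 in ear and 111 to 293 in shielded leaf. The difference of changes gave 0 to 23 at 10 min and 0 to 3 at 30 min for irradiated leaf against shielded leaf, 240 to 1430 at 10 min and 61 to 866 at 30 min for ear against irradiated leaf, and 30 to 236 at 10 min and 4 to 213 at 30 min for ear against shielded leaf.

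An array left out takes both of its RNAs with it. Shielded leaf without 0 min RNA 1 and 30 min RNA 4 gave 85 at 30 against 0 min, 3 at 30 against 10 min and 53 for ear against shielded leaf at 30 min. Shielded leaf without 30 min RNA 3 and 0 min RNA 2 gave 24 at 30 against 0 min, 0 at 30 against 10 min, 87 for ear against shielded leaf at 10 min, 4 for ear against shielded leaf at 30 min and 181 in the F test. Shielded leaf without 0 min RNA 3 and 10 min RNA 2 gave 212 at 10 against 0 min, 2 at 30 against 10 min, 66 for ear against shielded leaf at 10 min, 65 for ear against shielded leaf at 30 min and 167 in the F test. Shielded leaf without 10 min RNA 1 and 0 min RNA 4 gave 110 at 10 against 0 min, 67 at 30 against 0 min, 0 at 30 against 10 min, 30 for ear against shielded leaf at 10 min, 22 for ear against shielded leaf at 30 min and 111 in the F test. Shielded leaf without 10 min RNA 3 and 30 min RNA 2 gave 68 at 30 against 0 min, 1 at 30 against 10 min and 41 for ear against shielded leaf at 30 min. Shielded leaf without 30 min RNA 1 and 10 min RNA 4 gave 5 at 30 against 10 min and 106 for ear against shielded leaf at 10 min. Ear without 0 min RNA 1 and 30 min RNA 4 gave 366 at 10 against 0 min, 36 at 30 against 0 min, 6 at 30 against 10 min, 93 for ear against shielded leaf at 10 min, 6 for ear against shielded leaf at 30 min, 61 for ear against irradiated leaf at 30 min and 246 in the F test. Ear without 30 min RNA 3 and 0 min RNA 2 gave 1 at 30 against 10 min and 213 for ear against shielded leaf at 30 min. Ear without 0 min RNA 3 and 10 min RNA 2 gave 360 at 10 against 0 min, 1 at 30 against 10 min, 178 for ear against shielded leaf at 30 min and 405 for ear against irradiated leaf at 10 min. Ear without 10 min RNA 1 and 0 min RNA 4 gave 1 at 30 against 10 min and 186 for ear against shielded leaf at 30 min. Ear without 10 min RNA 3 and 30 min RNA 2 gave 371 at 10 against 0 min, 82 for ear against shielded leaf at 10 min, 158 for ear against shielded leaf at 30 min and 469 for ear against irradiated leaf at 10 min. Ear without 30 min RNA 1 and 10 min RNA 4 gave 72 at 30 against 10 min and 160 for ear against shielded leaf at 30 min. Irradiated leaf without 0 min RNA 1 and 30 min RNA 4 gave 8 at 30 against 10 min. Irradiated leaf without 30 min RNA 3 and 0 min RNA 2 gave 1128 at 10 against 0 min, 105 at 30 against 0 min, 18 at 30 against 10 min and 106 for ear against irradiated leaf at 30 min. Irradiated leaf without 0 min RNA 3 and 10 min RNA 2 gave 879 at 10 against 0 min, 12 for irradiated leaf against shielded leaf at 10 min, 364 for ear against irradiated leaf at 10 min and 314 for ear against irradiated leaf at 30 min. Irradiated leaf without 10 min RNA 1 and 0 min RNA 4 gave 695 at 10 against 0 min, 3 at 30 against 10 min and 240 for ear against irradiated leaf at 10 min. Irradiated leaf without 10 min RNA 3 and 30 min RNA 2 gave 2695 at 10 against 0 min, 321 at 30 against 0 min, 133 at 30 against 10 min, 23 for irradiated leaf against shielded leaf at 10 min and 1430 for ear against irradiated leaf at 10 min. Irradiated leaf without 30 min RNA 1 and 10 min RNA 4 gave 976 at 30 against 0 min, 1 at 30 against 10 min, 9 for irradiated leaf against shielded leaf at 10 min, 3 for irradiated leaf against shielded leaf at 30 min and 866 for ear against irradiated leaf at 30 min. Irradiated leaf without 30 min RNA 3 and 60 min RNA 2 gave 56 at 30 against 10 min and 5315 at 60 against 30 min. Irradiated leaf without 60 min RNA 1 and 30 min RNA 4 gave 1341 at 60 against 0 min, 56 at 30 against 10 min, 2954 at 60 against 30 min and 3498 in the F test.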

Other observations

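Chosen after the results were seen were the groups of ear-high and leaf-high probes, and the tests of dye bias, shared plants, the 2 RNAs of 30 min, noise between the 60 min arrays and the normalization within arrays. The tests of other splits, harvest and pooled spread were set before.

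Among probes at least 8-fold higher in ear than in shielded leaf at 0 min, those called in irradiated leaf were mostly higher at 10 and 30 min and mostly lower at 60 against 30 min, while most of the group passed no test. Of 1140 such probes, 134 rose and 12 fell at 10 min, and 79 rose and 2 fell at 30 min, a call rate of 12.8% and 7.11% against 4.62% and 1.69% of all probes. The median change was 0.08 and 0.10. Between 30 and 60 min 363 fell and 42 rose, with a median of -0.19 and a call rate of 35.6% against 23.2% of all probes. At 60 against 0 min 29 rose and 94 fell. The 10 and 30 min changes share the 0 min RNAs, and the changes to and from 30 min share 30 min RNAs, which alone correlates them. More rose than fell early, and more fell than rose later, in each of these comparisons with Agilent's processed signals, no background subtraction, median centring, the deposited value table and the separate-channel fit. Under median centring, for example, 80 rose and 1 fell at 10 min, 125 rose and 1 fell at 30 min, and 17 rose and 493 fell between 30 and 60 min. In shielded leaf 8 rose and 3 fell at 10 min, and in ear 17 rose and 19 fell, but the 0 min RNAs of these tissues also defined the group.

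Of 1272 probes at least 8-fold higher in shielded leaf than in ear, 53 rose and 114 fell in irradiated leaf at 10 min (median -0.03) and 11 rose and 57 fell at 30 min (median -0.04), a call rate of 13.1% and 5.35%, and most passed no test. Between 30 and 60 min 197 rose and 221 fell, of 1130 tested. These counts depend on the normalization. Under median centring 21 rose and 27 fell at 10 min (median 0.11), 61 rose and 12 fell at 30 min, and 30 rose and 539 fell between 30 and 60 min (median -0.60).

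The number of splits with as many calls includes the real one, so 1 is the lowest possible, and the number of counts tested was not adjusted for. In irradiated leaf, no other split called as many as the 1709 probes at 10 against 0 min (1 of 34 splits, highest other 1500) or the 7123 of the F test (1 of 100, highest other 6909), although other splits came close. Chance cannot be excluded for the 625 at 30 against 0 min (4 of 34, highest other 814) or the 32 at 30 against 10 min (6 of 34, highest other 425). In shielded leaf no other split called as many as the 358 at 10 against 0 min (1 of 34, highest other 14), the 140 at 30 against 0 min (1 of 34, highest other 21), the 11 at 30 against 10 min (1 of 34, highest other 3) or the 335 of the F test (1 of 100, highest other 226). In ear no other split called as many as the 592 at 10 against 0 min (1 of 34, highest other 406). The 691 of the F test (4 of 100) were under the limit set before, but other splits reached them, up to 1878, so chance is not excluded there. Nor can it be excluded for the 600 at 30 against 0 min (2 of 34, highest other 712) or the 3 at 30 against 10 min (13 of 34, highest other 536). Splits with several times the real count, in ear and in irradiated leaf at 30 against 10 min, point to a structure of the samples, whose source was not tested. The difference between leaf positions was 0 at 10 min (as many in 32 of 32 splits, highest other 3) and 0 at 30 min (32 of 32, highest other 1), and since any split reaches a count of 0, these splits decide nothing. At 0 min no other split came near the 22001 probes between ear and shielded leaf (1 of 35, highest other 7) or the 4062 between the leaf positions (1 of 35, highest other 22). Each of those other splits mixed the compared groups. A difference of batch would give the same result, so these splits do not separate it from tissue or leaf position.

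Most probes called in irradiated or shielded leaf changed the same way in both. The sign was shared by 91.4% of them at 10 min and 93.7% at 30 min, against 61.6% and 60.2% of all probes. A constant dye bias of the probes is argued against, since it cancels in the mean of both dye orientations, and changes averaged that way still correlated across probes between the leaf positions, with r = 0.643 at 10 min and 0.412 at 30 min, although single 30 min arrays of opposite orientation, less the dye term of the ear arrays, gave only r = -0.029 and 0.121. Plant-to-plant differences shared by leaves of the same plants stay open, since RNA numbers were not shown to identify plants, and so the r = 0.252 and 0.375 of changes from arrays with no RNA number in common decide nothing. Harvest time or handling cannot be told apart from UV-B, since 0 groups at 10 or 30 min came from plants without it. A signal that passes from exposed to shielded leaves may be the biological counterpart, and it was not tested.

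Many probes differed between 60 and 30 min in irradiated leaf, and the 2 RNAs of 30 min on the 60 min arrays are argued against as the whole cause, because on arrays without 60 min RNA they deviated from the other 2 RNAs of 30 min with a slope of -0.034 and -0.080 on the change (one for the probes that rose, the other for those that fell), where a slope of -1 would account for all of it. Noise that differs between the 2 arrays of 60 min is argued against too, because their changes, less the dye term of the other tissues, correlated across probes with r = 0.623, against -0.077 for the 2 arrays of 30 against 10 min. A spread pooled too small stays open for part of the calls, since 2118 probes passed with the spread of slide 2 alone, and the 0 that did for 30 against 10 min left the planned ratio without a base. The normalization within arrays stays open, since 82.4% of the called probes had the same sign under median centring and 4932 of 8542 were still called that way. Time under UV-B, which the design names, may be the biological counterpart, and with 2 RNAs it stays untested.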
